A study of Rattus norvegicus with 7 samples.

How the data were processed

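RNA of the liver of 18-month-old male rats treated with injections of human growth hormone (GH) was set against liver RNA of untreated rats of the same age on 7 arrays with 2 channels each. Per the labels, the treated RNA was in channel 2 on arrays 1, 2, 4 and 5 and in channel 1 on arrays 3, 6 and 7, the untreated RNA being in the other channel. The dose, the length of treatment, the dyes and the number of animals are not given in the sources used here. Because no label ties an array to an animal, p-values measure only the spread between arrays, which may be technical.

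Values came as 2 deposited tables, 1 per array design: a table of arrays 4 to 7 with 6240 clones from 65 plates of 96 wells (the 4-array table) and a table of arrays 1 to 3 with 3168 lines (the 3-array table). The latter held 3072 clone names from 32 plates, all of them also in the former; the clones of plate RNAA were listed again, in 96 lines with identical values, and were averaged into 1 value per clone. The values deposited by the authors were taken as log2 ratios and had a median near 0 on every array, from -0.028 to 0.012. Scanner, background correction, normalization and filter are not given in the sources used here. How missing values arose is not given either.

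Scale and sign were read from the values. On arrays 1 and 2 of the 3-array table, 2 to the power of the value lay on equal steps (within 0.1 of a step) for 99.83% and 100% of the values used, against at most 29.13% under base 10, base e or the inverse ratio. On array 3 the inverse ratio lay on such steps for 100% of the values, against 28.73% for the next best form. The deposited values of this table are thus base 2 logarithms of rounded ratios, centred by a constant per array, with the sign of array 3 turned relative to arrays 1 and 2. The 4-array table held no such steps (at most 25.03% under any form), so its log2 scale is taken from the 3-array table and its folds rest on that.

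The direction followed a rule set before the data were examined, like the tests and alternatives unless stated otherwise: where arrays of opposite orientation correlated above 0.1 within a table, the values were used as deposited. The median correlation across clones between arrays of opposite orientation was 0.621 in the 4-array table and 0.184 in the 3-array table. The latter is the midpoint of the only such pairs, arrays 1 and 3 (r = -0.150) and arrays 2 and 3 (r = 0.519). Their signs differ, so the rule was met in the 3-array table by the median alone. Neither labels nor values fix the overall sign, so positive ratios are called likely GH-treated over untreated, on the basis of the turned array 3 and of the usual ratio of channel 2 over channel 1. A clone-specific dye effect in values that had not been turned would give the same pattern, a single sign on arrays of both orientations.

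Each table was fitted by itself, since the tables were taken as normalized separately, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05) on clones with a value on at least 3 arrays. Clones with a single sign on all arrays and a mean change of at least 1.5-fold were counted beside it. A coefficient for channel orientation, the distance of each orientation from their common mean, was fitted in a separate model. The tables were compared by Pearson and Spearman correlation across clones, which are not independent replicates, and by the 2-sided Fisher exact test. Binomial intervals are exact (Clopper-Pearson, 95%). They count clones as independent trials, which they need not be, and do not measure the spread between arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the test of steps and the figures.

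The fit was tested on simulated tables with the missing values and array spreads of the real ones and 200 changed clones. In the 4-array table (2712 clones) it recovered 56.5% of changes of 1 on the log2 scale and 92.5% of changes of 2, with 8.87% and 5.61% of calls false. In the 3-array table (1191 clones) it recovered 74.0% and 100%, with 2.63% and 5.21% of calls false. The simulation drew errors independently between arrays and gave a changed clone the same change on every array. The real array 1 correlated with arrays 2 and 3 at -0.0391 and -0.150, so these shares need not hold for the real 3-array table. The number of arrays limits the precision of every value.

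The files do not pair the clone names with genes, and 0 of the 6240 names matched the gene table used. The pathway and cell marker lists chosen beforehand, the comparison by gene means and the gene symbols in the rule for named genes therefore could not be used, and clones took the place of genes. Of the rule, this remained: per table, at most 2 clones that rose and 2 that fell, those with the largest mean change past the threshold, or, where none passed in a direction, those with the smallest p and a single sign on every array. Alternatives were centring, centring with scaling, the orientation coefficient, the other turning, other minimum numbers of arrays, a robust prior, a threshold of 0.1, a test without moderation and leaving out each array. Array weights, single arrays against the 4-array mean, leaving out plates RNAA and RGIBA and the alternatives of the orientation count were added after seeing the data.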

Results

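Growth hormone acts on the liver, one of its main target tissues, and its secretion falls with age. The arrays asked how the liver transcripts of 18-month-old male rats differed between animals injected with human GH and untreated animals. On the arrays of the 4-array table, 2957, 2747, 2386 and 3730 of 6240 clones had a value (arrays 4 to 7). On those of the 3-array table, 1878, 1653 and 1377 of 3072 clones had a value (arrays 1 to 3). The treated RNA was in channel 2 on 4 arrays and in channel 1 on 3 arrays. Higher and lower, like rose and fell, stand for positive and negative log2 ratios, likely GH-treated over untreated, on the basis given with the processing; the folds of the 4-array table take its scale to be log2.

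In the 4-array table, a large set of clones had ratios that differed from 0, in both directions. That these are differences between treated and untreated rats is likely and not settled, because a dye effect in values left unturned was not excluded. Of 2712 clones tested with limma, 435 passed the adjusted threshold of 0.05, of which 182 were higher and 253 lower; the numbers were nearly even with centring and scaling (367 and 370), with array weights (432 and 433) and without array 7 (335 and 345). The median change was 0.99 on the log2 scale (1.98-fold) among those that rose and -0.89 among those that fell. At least 2-fold changes were found for 87 clones that rose and 89 that fell, and at least 4-fold changes for 13 and 6. All 435 had a single sign on every array that measured them, in both channel orientations.

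The clone with the largest mean ratio past the threshold, RNABQ26, had a mean log2 ratio of 4.69 ± 0.61 (SD, n = 3 arrays; limma adjusted p = 0.00398), which is 25.8-fold, with 4.05 on the lowest and 5.26 on the highest array. RNABD61 rose by 3.73 ± 1.59 (SD, n = 3; limma adjusted p = 0.0209), with arrays between 2.17 and 5.34, so its size was less precisely measured. Neither clone had a value on array 6. The most strongly reduced clone, RNABV24, had a mean log2 ratio of -3.87 ± 0.068 (SD, n = 4; limma adjusted p = 0.000151), with all arrays between -3.95 and -3.80. RNAB62 had a mean of -2.94 ± 0.43 (SD, n = 4; limma adjusted p = 0.00307), between -3.33 and -2.52. With the other turning none of these 4 clones passed, at 1.52 for RNABQ26, 0.17 for RNABD61, 0.055 for RNABV24 and -0.016 for RNAB62 (limma adjusted p = 0.999 for each). The files do not pair these clones with genes. None of the first 3 had a value on arrays 1 to 3; RNAB62 was at -1.59 on array 1 and at 1.34 and 1.84 on arrays 2 and 3.

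**Figure D1:**
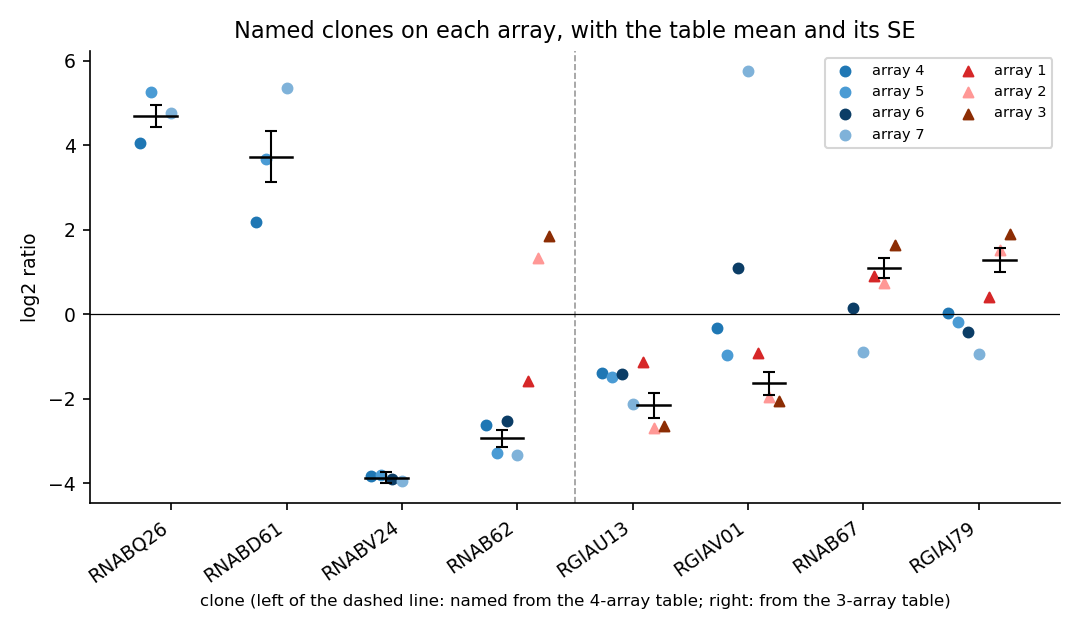
Log2 ratio (vertical axis, likely GH-treated over untreated) of each named clone (horizontal axis) on each array that measured it, with circles for arrays 4 to 7 and triangles for arrays 1 to 3; the black line and bar give the mean of the clone's table and its limma SE. RNABV24 lay between -3.95 and -3.80 on all 4 arrays, while RNAB62 was negative on arrays 4 to 7 and 1 and positive on arrays 2 and 3.

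At an unadjusted p under 0.05 there were 968 clones, where 136 would be reached by chance. Counted without a model, 660 clones had a single sign on all their arrays and a mean change of at least 1.5-fold, 348 higher and 312 lower; a single sign alone was found in 51.1% of the tested clones, where even odds give 16.3%. The number of clones past the threshold depended on single arrays: it was 169 without array 4, 54 without array 5, 91 without array 6 and 680 without array 7, and 165, 54, 90 and 358 of these were among the 435. Without array 7 the count with a single sign was 416, and a test without moderation called 49 clones.

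No clone of the 4-array table passed for a difference between the channel orientations: limma called 0 clones for the orientation coefficient. An unadjusted p under 0.05 was found for 243 clones, where 136 would be reached by chance. The difference between the orientations had a median absolute size of 0.34 on the log2 scale, and the ratio fitted beside it 0.35. With array 6 left out, 562 clones passed, so this count rested on an array whose partner in orientation, array 7, was the most widely spread. The SD of log2 ratios was 1.25 on array 7 and 0.62, 0.65 and 0.58 on arrays 4, 5 and 6.

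In the 3-array table, few clones differed from 0 across arrays 1, 2 and 3. Of 1191 clones, 2 passed the limma threshold, both lower, and 95 had an unadjusted p under 0.05, where 59.6 would be reached by chance. RGIAU13 had a mean log2 ratio of -2.16 ± 0.88 (SD, n = 3; limma adjusted p = 0.0289), and it was also negative on arrays 4 to 7, between -2.12 and -1.40. RGIAV01 had a mean of -1.64 ± 0.63 (SD, n = 3; limma adjusted p = 0.0439), and it was at -0.33 and -0.96 on arrays 4 and 5 but at 1.10 on array 6 and 5.75 on array 7. The clones with the smallest p among those with positive values on every array did not pass: RNAB67 was at 1.09 ± 0.48 and RGIAJ79 at 1.28 ± 0.78 (SD, n = 3; limma adjusted p = 0.208 for both). Both passed under 4 of 12 alternatives: with the orientation coefficient, with at least 2 arrays, with array weights and without array 1. Those fits called more higher than lower clones: 31 and 19, 20 and 10, 18 and 12, and 43 and 29. With the orientation coefficient or without array 1, a clone has 1 residual degree of freedom, so p leans on the spread pooled over clones. RNAB67 was at 0.16 on array 6 and -0.89 on array 7, and RGIAJ79 lay between -0.94 and 0.029 on arrays 4 to 7.

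A single sign on all arrays with a mean change of at least 1.5-fold was found for 50 clones of the 3-array table, 17 higher and 33 lower; a single sign alone was found in 25.9% of clones, where even odds give 25%. The limma count was 72 without array 1, 0 without array 2 (30 at an unadjusted p under 0.05) and 10 without array 3, and the count with a single sign was 162, 82 and 91. A single sign is easier to reach on the fewer arrays that remain, so these counts cannot be compared directly with the 50. Both clones past the threshold lost it without array 2, with adjusted p = 0.999, at mean log2 ratios of -1.90 for RGIAU13 and -1.48 for RGIAV01. For the orientation coefficient 9 clones passed limma, all of them with ratios lower on arrays 1 and 2 than on array 3, the only array of its orientation in that table.

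The arrays of the 3-array table did not share a common profile, and array 1 resembled arrays 4, 5 and 6. Across clones, array 1 correlated with arrays 4, 5 and 6 at r = 0.499, 0.495 and 0.503 and with array 7 at 0.168. It correlated with arrays 2 and 3 of its own table at -0.0391 and -0.150. Arrays 2 and 3 correlated with each other at 0.519 (rho = 0.249) and with arrays 4 to 7 between -0.139 and -0.0108. Within the 4-array table, r lay between 0.503 and 0.795. Over the 775 clones measured on all 7 arrays, array 1 had r = 0.663, 0.627 and 0.654 with arrays 4, 5 and 6 and 0.252 with array 7.

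**Figure D2:**
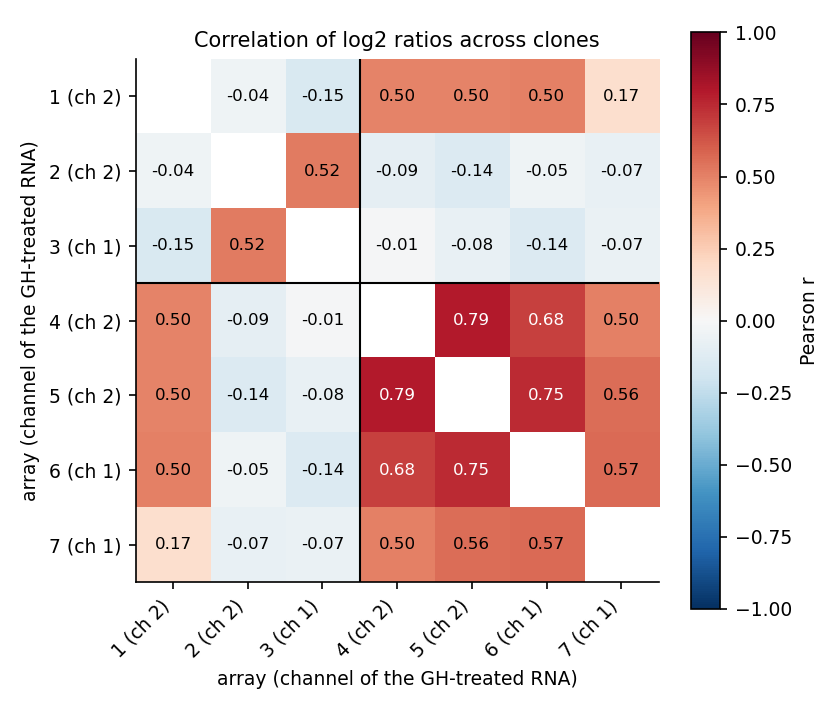
Pearson r across clones between the log2 ratios of each pair of arrays, with the array and the channel of its treated RNA on both axes; the lines part the 3-array table (1 to 3) from the 4-array table (4 to 7). Array 1 has r near 0.50 with arrays 4, 5 and 6, and arrays 2 and 3 have r = 0.52 with each other and values from -0.14 to -0.01 with arrays 4 to 7.

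Clones that differed in the 4-array table moved the same way on array 1 and not on arrays 2 and 3. Of the 435 clones, 212 had their name in the 3-array table too. On array 1, 181 of 194 with a value had the sign of the 4-array mean (93.3%, interval 88.8% to 96.4%), against 65.1% of the clones that did not pass. Clones that had risen had a median log2 ratio of 0.50 there, and those that had fallen -0.47. On array 2, 79 of 185 had that sign (42.7%, interval 35.5% to 50.2%), and on array 3, 72 of 167 (43.1%, interval 35.5% to 51.0%), against 47.8% and 49.5% of the clones that did not pass. The correlation with the 4-array mean was 0.462 on array 1, -0.0947 on array 2 and -0.0943 on array 3. The tables were taken as normalized separately, so signs and correlations were compared, not levels.

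**Figure D3:**
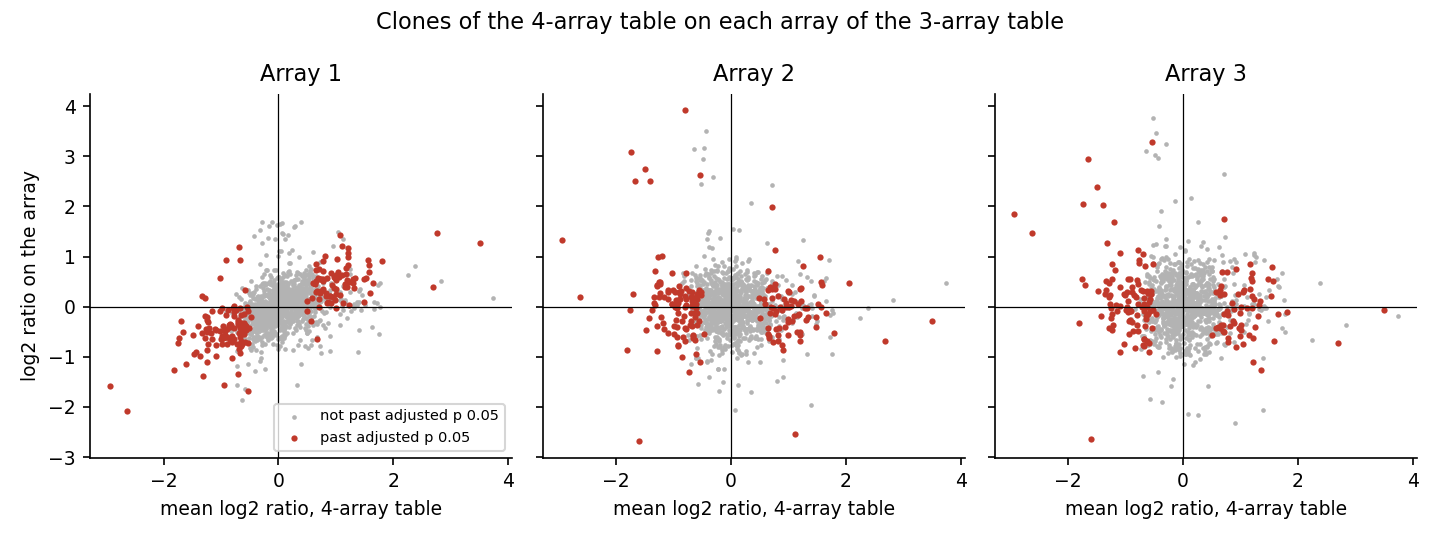
Log2 ratio on arrays 1, 2 and 3 (vertical axis, a panel per array) against the mean log2 ratio of the 4-array table (horizontal axis); each point is a clone, red where it passed the adjusted threshold of 0.05 in the 4-array table. On array 1, 181 of 194 red points lie on the same side of 0 as their mean, on array 2 79 of 185 and on array 3 72 of 167.

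The mean ratios of the tables were only weakly related. Across 999 clones tested in both, r was 0.0924 and rho 0.185. An unadjusted p under 0.05 in both tables was found for 32 clones, where independent lists give 27.5; 23 of them had the same sign in both (5 higher, 18 lower) and 9 were lower in the 4-array and higher in the 3-array table (Fisher exact p = 0.00994, 2-sided). Of 775 clones measured on all 7 arrays, 73 had a single sign throughout, where independent tables give 49.1, and 10 had opposite single signs in the tables, where 49.3 are given. The correlation was -0.105 without array 1, 0.217 without array 2, 0.230 without array 3 and 0.158 without array 7. The share with the same sign was 43.75% without array 1 (Fisher exact p = 1.00), 59.3% without array 3 (p = 0.628) and 61.5% without array 6 (p = 0.0527). It was 100% without array 2 (10 clones, Fisher exact p = 0.00476), 72.7% without array 4 (p = 0.0152), 77.3% without array 5 (p = 0.00957) and 75.0% without array 7 (p = 0.000338).

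Arrays 2 and 3 shared a small set of clones that changed strongly and the same way on both. Of 1307 clones measured on both, 39 differed at least 2-fold in the same direction, 27 higher and 12 lower, where independence gives 2.28, and 0 did so in opposite directions. Tested plate by plate over all 32 plates, after the values were seen, plate RNAB held 9 of the 39 among 54 clones measured on both arrays (Fisher exact test, 2-sided, adjusted p = 0.000465) and plate RNAA 9 among 62 (adjusted p = 0.000746); the lowest adjusted p of the other plates was 0.344. The correlation of 0.519 between arrays 2 and 3 was 0.221 without the 39 clones, whose choice by likeness by itself lowers it. Of the 27 higher clones, 23 had a value on array 1, and 20 of these were below 0 there.

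The wells of plates RNAA and RGIBA matched between the tables better in reversed order than in their own, a check chosen after the values were seen. For 30 of the 32 shared plates, the number of arrays with a value per well correlated between the tables at 0.348 to 0.842, above the r of that plate with any other plate. Plate RNAA had r = -0.143 and plate RGIBA r = 0.196, but with the wells in reversed order these were 0.443 and 0.613, where the highest r among 2048 pairs of different plates was 0.325 in the wells' own order and 0.350 in reversed order. Without these plates, 174 of 180 clones (96.7%) had the sign of the 4-array mean on array 1, 71 of 172 on array 2 and 68 of 156 on array 3. Which table has the wells of these plates in the right order is not given in the sources used here; none of the named clones lies on either.

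**Figure D4:**
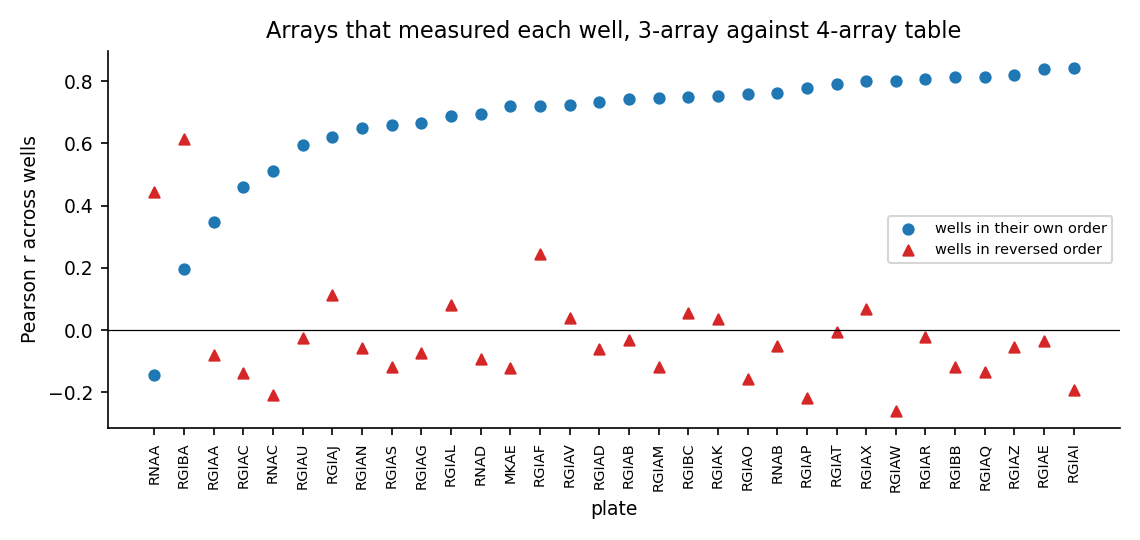
Pearson r across the 96 wells (vertical axis) between the number of arrays with a value per well in the 3-array and in the 4-array table, for each of the 32 shared plates (horizontal axis), with the wells in their own order (circles) and in reversed order (triangles). Plates RNAA and RGIBA have higher r in reversed order (0.443 and 0.613) than in their own (-0.143 and 0.196).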

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

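Chosen after the result was seen were the tests of row register by measured clones, of a turned sign from the correlations of arrays 2 and 3, of an unturned dye effect and of the order of wells, and the counts over turned arrays. The tests of dim spots, of exchanged plates and of the sign of clones changed in both tables were chosen before. Plates RNAA and RNAB, on which the test of exchanged plates was run, were picked after the values were seen.

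Array 7 lay far from the other arrays of the 4-array table in spread, with an SD of 1.25 and an interquartile range of 1.27 on the log2 scale. Clone RGIAU13 was at -2.12 on array 7, apart from arrays 4, 5 and 6 (-1.40, -1.49 and -1.41). Of 10 groups of 4 values looked at, 3 held such a value, and chance gives about 1 in 20. All 3 concern array 7, and the SD and the interquartile range measure the same spread, so they are not independent. A total of 10 clones had a single sign on arrays 4 to 7 and the opposite sign on arrays 1 to 3, fewer than the 49.3 that independent tables give; this difference was not tested.

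Array 1 stood apart from arrays 2 and 3 of its table and resembled arrays 4 to 6, and array 7 less (r = 0.168). Rows out of register on arrays 2 and 3 are argued against by the clones with a value, whose phi coefficient with arrays 4 to 7 was at least 0.479, and a turned sign is argued against by correlations with the 4-array mean of -0.0947 and -0.0943, which lie near 0, where a turned sign would give values about as far below 0 as the 0.462 of array 1 lies above it. If noise of dim spots set array 1 apart, its r with arrays 2 and 3 should rise among clones measured on all 7 arrays. Over these 775 clones it reached at most -0.0099. That argues against such noise only where missing values mark dim spots, and how they arose is not given. Arrays 2 and 3 had opposite orientations and, with array 3 turned, r = 0.519, so a dye effect that ran through both would have given a negative value. That arrays 2 and 3 may hold RNA of other animals than the rest, or another RNA than labelled, stays open and was not tested.

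In the 4-array table, clones had a single direction on arrays of both orientations. A dye effect in values left unturned would give the same pattern, and it would also give arrays 1 and 2, which were not turned, a positive correlation with the 4-array mean. Array 1 had 0.462 and array 2 -0.0947. An effect of GH would give both a positive correlation too, since these unturned arrays had the treated RNA in channel 2. An unturned dye effect and an effect of GH therefore cannot be told apart by this test, whatever its values. The turned sign of array 3 in the sister table is consistent with values turned before deposit in both. With the other turning 0 clones passed limma (24 at an unadjusted p under 0.05), which either reading gives.

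A total of 6 clones were past the threshold and at least 2-fold lower in the 4-array table and at least 2-fold higher on arrays 2 and 3, and all 6 were below 0 on array 1; 5 lie on plates RNAA and RNAB. An exchange of these plates between the printings is argued against by plate RNAB, whose measured wells matched themselves (phi 0.526 and 0.628 on arrays 2 and 3) better than those of plate RNAA (0.298 and 0.306, and 0.162 and 0 the other way round), although the median phi over both plates, 0.288, missed the bound of 0.3 set beforehand. Plate RNAA does not argue against it: its wells in their own order matched themselves at phi -0.113 and -0.0930, below the 0.298 and 0.306 with plate RNAB. A reversed order of the wells of plate RNAA in a table (r = 0.443 reversed, -0.143 in its own order) does not account for its clones here, RNAA44 and RNAA53. Wells 44 and 53 change places with each other when 96 wells are reversed. Both clones were lower in the 4-array table (-1.40 and -1.74) and higher on array 2 (2.51 and 3.09) and array 3 (2.02 and 2.04), so they stay opposite after reversal. For the clones of the other plates, wells matched in their own order (r at least 0.760). A turned sign on arrays 2 and 3 is argued against by all clones past the threshold, of which 42.7% and 43.1% kept the sign of the 4-array mean there and 93.3% on array 1; of the 7 changed 2-fold in both, 14.3% ran the same way, too few to decide (exact interval 0.361% to 57.9%). Whether RNA of other animals gave these values was not tested.

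With signs of single arrays or pairs turned, the 4-array table has 8 splits, of which 1 gave as many as 435 clones, the real one; the highest other gave 0. The 3-array table has 4 splits, of which 2 gave 2 clones or more; the real one gave 2 and the highest other, with arrays 2 and 3 turned together against array 1, gave 18. In both tables the splits are too few for a share under 0.05. The 18 clones point to a structure of the arrays, in which array 1 runs apart from arrays 2 and 3. A turned sign of arrays 2 and 3 would also raise this count, so the split does not argue against it. Of the 27 clones at least 2-fold higher on both arrays, 18 were below 0 in the 4-array table. Among the lower ones, 11 had a mean there and 4 of these were below 0.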

How the results depend on the processing

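Array weights, single arrays, plates left out and every alternative of the orientation count were chosen after seeing the data. In the 4-array table the 435 clones became 737 with centring and scaling, 746 at a threshold of 0.1, 865 with array weights, 49 without moderation and 0 with the other turning (24 at an unadjusted p under 0.05); all 435 were among the 737 and the 865, and 44 among the 49. The other 5 alternatives gave 307 to 544. Leaving out an array gave 54 (array 5) to 680 (array 7). The 660 clones with a single sign became 236 at 2-fold and 40 with the other turning, and 416 (array 7) to 670 with an array left out. The orientation count was 0 to 562 (array 6).

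In the 3-array table the 2 clones became 1 with centring, 4 with a robust prior, 4 at a threshold of 0.1, 30 with at least 2 arrays, 30 with array weights, 50 with the orientation coefficient, 0 without moderation (61 at an unadjusted p under 0.05) and 0 with the other turning (40). Leaving out an array gave 0 (array 2) to 72 (array 1). The 50 clones with a single sign became 12 at 2-fold and 20 with the other turning. With an array left out, where fewer arrays have to share the sign, they became 82 to 162 (array 1). The orientation count became 5 with centring. Its fit without an array leaves no residual degree of freedom, and a value on every array is the setting already used.

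The correlation of the tables was -0.105 (without array 1) to 0.230 (without array 3) and 0.462 for array 1 alone; without plates RNAA and RGIBA it was 0.105 (958 clones). With the other turning, RNABV24 came to 0.055 and RNAB67 to -0.0035, since opposite values then cancel; the cause of other moves was not tested. RNABV24 passed under 13 of 14 alternatives, RNAB62 under 13 of 14, RNABQ26 and RNABD61 under 8 of 10, RGIAU13 under 9 of 12 and RGIAV01 under 8 of 12, while RNAB67 and RGIAJ79, not past the threshold, passed under 4 of 12 each, with adjusted p from 0.000102 and 1.95e-07 up to 0.999 over all 12. The lowest values came from fits with 1 residual degree of freedom per clone, which lean on the spread pooled over clones. A test without moderation gave both clones an adjusted p of 0.897. Gene list alternatives and the probe with the smallest p per gene were not run, as clones have no gene names. Missing values limit both tables: 826 of the 2712 clones were measured on 3 of the 4 arrays. Each array already set treated against untreated RNA. No label pairs arrays of opposite orientation with each other, so no such pairing entered the fits.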

Other observations

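The tests by plate and by clone prefix were chosen after the result of the 4-array table was seen. Clones that fell in the 4-array table were unevenly spread over the sets of clones, those that rose were not shown to be. Clone names begin with RGI, RNA or MKA; what the prefixes stand for is not given in the sources used here. Of the tested clones, 11.4% of 1441 with the prefix RNA and 6.92% of 1257 with RGI passed the limma threshold and fell (Fisher exact p = 6.45e-05, 2-sided), while 6.45% and 6.92% rose (p = 0.643). Of 65 plates, each tested in both directions (130 Fisher exact tests, Benjamini-Hochberg adjusted within a direction), only plate RNAB passed, with 12 of its 39 tested clones lower (adjusted p = 0.00859). The lowest adjusted p for clones that rose was 0.164.

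On array 1, 404 clones had a value there and on neither other array of its table, and 28.2% of these lay at 1 or above on the log2 scale, against 0.42% of the 1191 clones measured on all 3 arrays. The 404 clones did not enter the fit of the 3-array table.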
